A study of Halobacterium salinarum NRC-1 with 5 samples.

How the data were processed

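Transcript levels of the halophilic archaeon Halobacterium NRC-1 were measured on 2-colour oligonucleotide arrays covering 2484 genes. The scanner output of 7 scans was used, and it spans 4 comparisons. TMAO growth against standard aerobic growth has 1 scan, arginine growth against TMAO growth has 2, arginine growth against aerobic growth has 2, and a dmsR deletion against its parent has 2 with opposite dyes. A bat deletion against its parent was read only from the authors' merged column, and its array scans were not analysed here. TMAO is trimethylamine N-oxide, which the cells can use in place of oxygen to take up electrons.

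The deposited scanner values are spot intensities, the mean pixel signal of a spot and the median of its local background in Cy3 and Cy5, produced with Agilent Feature Extraction version 8.1.1.1 or an earlier version per the file headers. The same files carry a log10 ratio of Cy5 over Cy3 after background subtraction and dye normalization, per the file headers. The authors' deposited value table holds 1 value per gene and comparison, and set against the scanner files these values are on a log2 scale. Which steps led from the scans to that table is not given in the sources used here. Its column medians were 0.00 for the dmsR deletion, -0.04 for the bat deletion, 0.02 for TMAO against O2, -0.01 for arginine against TMAO and -0.00 for arginine against O2. Over genes other than the 7 with left-out spot records, the columns correlated with the recorded ratios turned by the dye labels at r = 0.91 for TMAO against O2, 0.68 for arginine against TMAO, 0.90 for arginine against O2 and -0.82 for the dmsR deletion. Centring of the table, and the directions of its dmsR and bat columns, stay unknown. The bat column is printed in the direction of its label. In 1 dmsR file the first line of column names has 90 entries against the 87 that fit its records, so the second line of names was used.

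Each array carried 8075 gene spots for 5762 probes, with a median of 3 probes per gene. Gene names are those of the array design: 1019 genes had a symbol other than vng and a number, and 52 had no symbol. Because 87 genes share a probe sequence with another gene, those are named only as uncertain. The annotation table at hand belongs to another strain and was not used. The median gene spot stood 2.48 to 3.7 times above its local background on the dmsR arrays. On the growth arrays the range was 5.06 to 37.82, and at most 3.48% of gene spots in a channel of a fitted growth array were saturated. The small number of arrays limits the precision.

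Intensities were background-corrected by normexp with an offset of 50 and normalized within arrays by loess in limma 3.58.1 under R 4.3.3, with control spots and spots with outlier flags at weight 0. Files were read with python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. Outlier flags removed 174 gene spots. Spots of 1 probe were averaged and a gene's value was the median over its probes; in 506 of 1856 genes with several probes, the probes spanned over 1 log2 unit on at least 1 array. A single linear model with coefficients for TMAO, arginine, the dmsR deletion and dye was fitted to all arrays with lmFit and eBayes, so the comparisons share 1 spread per gene. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The labels do not say that replicate arrays came from separate cultures, so p-values measure only the spread between arrays. A comparison with a single array is tested on the assumption that it varies like the others.

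The fit departs from the plan in 2 ways, both chosen after the data, including the values near dmsA and the closure of the 3 growth comparisons, had been seen. First, the TMAO against O2 scan and replicate 1 of arginine against TMAO were 2 scans of 1 array: deviations of 4626 repeated spots from their probe means correlated at 0.99 in Cy3 and 0.97 in Cy5, against at most 0.32 and 0.4 in the other 20 pairs of scans. The array was counted once, under its TMAO against O2 label, which leaves every comparison at least 1 array. Second, 50 spot records in the dmsR files, 25 in each, were left out because the product of their Cy3 and Cy5 dye-normalization factors lay over 1 percent from that of their scan. The fit therefore had 6 arrays, 2 residual degrees of freedom and 3.7 prior degrees of freedom. For dmsA, vng828, hmoA, moz and vng832, every record on both dmsR arrays was left out. These genes were fitted on the growth arrays alone, with fewer residual degrees of freedom. As planned, with 7 scans and all records, limma called 915 genes for TMAO against O2, 0 for arginine against O2, 317 for arginine against TMAO and 0 for the dmsR deletion.

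Before the data were examined, 31 gene lists, the design, the alternatives and the rule for named genes were fixed. The rule takes the targeted genes; all members of the lists for dms genes, arginine fermentation and the purple membrane; the 10 largest changes each way among genes past the threshold with 1 sign on all arrays of the comparison; the 10 highest and 10 lowest values of the bat column; and up to 4 members of each called list. Where fewer than 5 passed, the 5 largest same-sign values were taken as values that did not pass. Of the lists, 28 had at least 3 measured genes and were tested with camera, two-sided, at a preset inter-gene correlation of 0.01. P-values were adjusted over 112 pairs of list and comparison, and the lists were tested again with an estimated correlation. With an estimated correlation, camera uses the few residual degrees of freedom of the fit, so that test has little power whatever the correlation.

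The procedure was tested on simulated log ratios of 2484 genes with the measured spread and 200 changed genes. For TMAO against O2, 68% of genes changed by 1 log2 unit and 86% of those changed by 2 were recovered, and 2.22% of calls were false. For arginine against O2 the same shares were 82%, 92% and 8.37%. For arginine against TMAO they were 50%, 88% and 4.12%, and for the dmsR deletion 78%, 96% and 5.08%. For TMAO against O2, all 10 shifted lists were recovered and 0 of 20 unshifted lists were called. The simulated genes varied independently and the lists were drawn at random. The simulation therefore does not test how often lists of genes that vary together are called without a shift.

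Alternatives were no dye coefficient, growth and dmsR arrays fitted apart, the dmsR arrays averaged, no background correction, the recorded log ratio, median centring, Aquantile scaling, a filter on dim probes that kept 2454 genes, means over probes, array weights, a size threshold, each array left out, and 6 alternatives on the double scan and the left-out records that were chosen after seeing the data. The arrays lay on 4 slides, and terms for slides left 0 residual degrees of freedom.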

Results

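The series asked how transcript levels of Halobacterium NRC-1, an extremely salt-loving archaeon, differ between growth with oxygen, with TMAO and with arginine, and between deletions of the regulators dmsR and bat and their parents. Expression ratios were measured for 2484 genes. After 1 array scanned under 2 labels was counted once, TMAO against O2 had 1 array, arginine against TMAO 1, arginine against O2 2 and the dmsR deletion 2. The bat deletion was represented by the authors' merged values.

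In cells grown with TMAO, some transcripts of the purple membrane and of gas vesicles were higher than in aerobic cells, and 37 of 55 for ribosomal proteins, 7 of 8 for ATP synthase and 9 of 17 for cobalamin synthesis were lower. The largest rise was that of bop, which encodes bacterioopsin, the protein of the light-driven proton pump, at 12.6-fold (log2 ratio 3.66 ± 0.43 SE, limma adjusted p = 0.00616). Its log2 ratio on the single array of this comparison was 3.10. The gas vesicle structural genes gvpA1 and gvpA2 rose by 2.26 ± 0.26 and 2.28 ± 0.25 on the log2 scale. The gene dmsA, encoding the catalytic subunit of the TMAO and dimethyl sulfoxide reductase, rose 3.10-fold (log2 1.63 ± 0.26, adjusted p = 0.0169). Its probes disagreed widely, spanning 3.64 log2 units on at least 1 array. All records of dmsA on the dmsR arrays were left out, so it was fitted on the growth arrays alone. In that fit its TMAO value comes only from the arrays with arginine. On the TMAO against O2 array itself the log2 ratio of dmsA was 1.27.

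Among the 6 measured purple membrane genes, bop, brp (0.99, a bacterioopsin-related protein) and crtB1 (0.71, phytoene synthase) rose and 3 did not pass the test. Adjusted over the list alone, 4 rose. The values that did not pass were 0.48 for blp, 0.04 for bat and -0.16 for blh. The list as a whole was not called (camera adjusted p = 0.135). Of 27 gas vesicle genes, 10 rose, 1 fell and 16 did not pass; adjusted over the list alone, 11 rose and 2 fell, and the list was not called (adjusted p = 0.116). Besides gvpA1 and gvpA2, gvpC1, which encodes the protein that stiffens the vesicle, rose by 1.98 ± 0.14. Of 4 arginine fermentation genes, arcC, which encodes carbamate kinase, fell to a log2 ratio of -1.29 ± 0.19 (adjusted p = 0.0102). The values of arcB (-0.56), arcA (-0.01) and arcR (0.09) did not pass, and adjusted over the list alone 0 rose and 2 fell. Genes that the array design gives only a number and that rose were vng2626 (2.75), vng1007 (1.98) and vng1468 (1.87). The values of vng5015 (2.44), vng112 (2.38) and vng5114 (2.35) are uncertain, since their probe sequences occur in more than 1 gene.

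The ribosomal protein list was called toward lower values (adjusted p = 2.6e-19; adjusted p = 0.641 with an estimated correlation). Of its 55 genes, 37 fell, 0 rose and 18 did not pass; adjusted over the list alone, 45 fell. The median log2 ratio was -1.66, and the lowest values were those of rpl14p (-2.76 ± 0.32), rpl5p (-2.59 ± 0.28), rps17p (-2.58 ± 0.30) and rpl29p (-2.49 ± 0.28), followed by rps14p (-2.47) and rpl19e (-2.46). Of 8 ATP synthase genes, 7 fell, over all genes and adjusted over the list alone, with a median of -1.51 and an adjusted p = 1.3e-05 (adjusted p = 0.641 with an estimated correlation). Its lowest members were atpK (-2.70 ± 0.22), atpI (-2.36 ± 0.13), atpC (-1.70) and atpA (-1.52). Of 17 cobalamin synthesis genes, 9 fell and 8 did not pass; adjusted over the list alone, 1 rose and 10 fell. Examples were cbiM (-2.59 ± 0.36), cbiN (-2.41 ± 0.25), cbiT (-1.98) and cbiF (-1.77), and the list's adjusted p = 8.1e-04 (adjusted p = 0.641 with an estimated correlation).

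Of 17 citric acid cycle genes, 7 fell, and adjusted over the list alone 9 did (list adjusted p = 5.2e-04; adjusted p = 0.641 with an estimated correlation). Its lowest members, korA (-1.16), korB (-1.09) and porB (-0.88), encode oxidoreductases that pass electrons from 2-oxoacids to ferredoxin, and sucC (-1.06) encodes a succinyl-CoA synthetase subunit. Of 11 genes of the NADH dehydrogenase-like complex, 1 rose and 4 fell, among them ndhG1 (-1.23) and nolB (-1.20); adjusted over the list alone 1 rose and 6 fell (adjusted p = 0.0205; adjusted p = 0.823 with an estimated correlation). Of 7 RNA polymerase genes, rpoK (-2.37), rpoN (-1.78), rpoH (-0.95) and rpoM (-0.74) fell, and adjusted over the list alone 4 fell (adjusted p = 0.0346; adjusted p = 0.641 with an estimated correlation). Of 20 aminoacyl-tRNA synthetase genes, 6 fell, among them pheS (-1.29) and aspS (-1.06), and adjusted over the list alone 7 fell (adjusted p = 0.00645; adjusted p = 0.748 with an estimated correlation). Also lower were vng1699 (-2.77) and vng788 (-2.49). In all, limma called 627 of 2484 genes, 335 higher and 292 lower, a share of 53.4% higher that became 46.5% with median centring and 34% among the 197 genes with a log2 ratio of at least 1 in size. The count depended on single arrays: it was 0 without the TMAO against O2 array, without the arginine against TMAO array or without either dmsR array, and 982 or 972 without replicate 1 or replicate 2 of arginine against O2. Fitting growth and dmsR arrays apart is, for the growth comparisons, the same fit as leaving out either dmsR array, and gave the same 0. With no dye coefficient the count was 1012.

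In arginine-grown cells, dmsA, 2 of 4 arginine fermentation genes and a few electron transport genes were higher than in aerobic cells, and 5 of 17 cobalamin synthesis genes and the ribonucleotide reductase genes nrdA and nrdB1 were lower. The largest rise was that of dmsA, at 8.72-fold (log2 3.12 ± 0.30 SE, adjusted p = 0.0303, 3.25 and 3.72 on the 2 arrays). Since dmsA was fitted on the growth arrays alone, its p-value rests on fewer arrays than those of most genes. In that fit the 3.12 comes only from the TMAO against O2 and arginine against TMAO arrays, at 1.27 and 1.85. The gene arcB, encoding ornithine carbamoyltransferase, rose 5.72-fold (2.51 ± 0.16, adjusted p = 0.00776), and arcC rose 3.42-fold (1.78 ± 0.18, adjusted p = 0.0225). The largest falls were those of nrdA (-2.34 ± 0.32) and nrdB1 (-2.30 ± 0.24).

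Of the 4 arginine fermentation genes, 2 rose and 2 did not pass, and adjusted over the list alone 3 rose. The value of arcA, encoding arginine deiminase, was 1.05 ± 0.18 (adjusted p = 0.0649), and that of arcR -0.08. The list's adjusted p = 5.2e-04 (adjusted p = 0.641 with an estimated correlation). Of 9 terminal oxidase genes, coxB2 (2.41 ± 0.22) and coxA1 (1.59 ± 0.19), which encode cytochrome oxidase subunits, rose and 7 did not pass; adjusted over the list alone 2 rose (adjusted p = 0.00217; adjusted p = 0.641 with an estimated correlation). Of 5 halocyanin and cytochrome b genes, hcpB, encoding a blue copper electron carrier, rose by 2.62 ± 0.18, and adjusted over the list alone 3 rose (adjusted p = 3.8e-04; adjusted p = 0.641 with an estimated correlation). Other genes that rose were nhaC3 (2.05), of the peptide and amino acid transport list, pan1 (2.02), encoding the proteasome-activating nucleotidase, vng1380 (1.32) and vng146 (1.21). Of 13 archaella and chemotaxis genes, flaA2 (1.09), encoding a filament protein, rose, and adjusted over the list alone 1 did (adjusted p = 0.00599; adjusted p = 0.641 with an estimated correlation).

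Of 17 cobalamin synthesis genes, 5 fell and 12 did not pass, and adjusted over the list alone 11 fell. The 5 were cbiN (-2.22 ± 0.23), cbiT (-2.07 ± 0.19), cbiF (-1.87 ± 0.12), cbiQ (-1.39) and cbiL (-1.19), and the list's adjusted p = 4.3e-10 (adjusted p = 0.641 with an estimated correlation). Also lower were carA (-1.50), encoding a carbamoyl phosphate synthase subunit, korA (-1.36) and vng1559 (-1.54). Gas vesicle genes (median -0.14, adjusted p = 0.00799; adjusted p = 0.641 with an estimated correlation), ribosomal protein genes (median -0.27, adjusted p = 0.00281; adjusted p = 0.748 with an estimated correlation) and oxidative stress genes (median -0.17, adjusted p = 0.0142; adjusted p = 0.641 with an estimated correlation) were called toward lower values with 0 members past the gene test. Adjusted over the list alone, 7, 0 and 2 of these fell. The purple membrane list was not called (adjusted p = 0.14), and 0 of its genes passed; adjusted over the list alone 2 rose. Its values were bop 1.74 ± 0.40 (adjusted p = 0.135), brp 0.76, crtB1 0.17, bat 0.05, blp -0.00 and blh -0.05. In all, limma called 28 genes, 16 higher and 12 lower, with 381 at an unadjusted p under 0.05. The share of 57.1% higher became 43.2% of 37 calls with means over probes and 44.7% of 356 with no dye coefficient. With median centring it was 60.6% of 33. The count was 0 with all 7 scans, without either dmsR array or with growth and dmsR arrays fitted apart, 1 without the TMAO against O2 array or the arginine against TMAO array, 284 or 313 without replicate 1 or 2, and 356 with no dye coefficient.

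In the direct comparison of the TMAO and arginine cultures, 2 of 4 arginine fermentation genes and 2 of 8 ATP synthase genes were higher with arginine. Higher with TMAO were 2 of 27 gas vesicle genes. The genes arcB and arcC were higher with arginine by 3.07 ± 0.23 and 3.07 ± 0.26 on the log2 scale (adjusted p = 0.0218 and 0.0222), at 3.20 and 3.10 on the array of this comparison. The gene gvpC1 was lower with arginine at -1.75 ± 0.19 (adjusted p = 0.0293) and gvpO1 at -1.35 ± 0.17. The purple membrane genes did not pass, with bop at -1.91 ± 0.59 (adjusted p = 0.133), crtB1 at -0.54, blp at -0.48, brp at -0.23, bat at 0.01 and blh at 0.11, and adjusted over the list alone 0 did (list adjusted p = 0.355).

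Of 4 arginine fermentation genes 2 rose, and adjusted over the list alone 3 did; arcA stood at 1.06 ± 0.26 and arcR at -0.18 (list adjusted p = 0.0058; adjusted p = 0.641 with an estimated correlation). Of 8 ATP synthase genes, atpB (1.74 ± 0.21) and atpI (1.73 ± 0.18) rose, and adjusted over the list alone 7 did (adjusted p = 1.5e-06; adjusted p = 0.641 with an estimated correlation). Of 55 ribosomal protein genes, rps11p (1.56 ± 0.19) rose over all genes and 36 rose adjusted over the list alone, with a median of 1.38 (adjusted p = 4.4e-20; adjusted p = 0.641 with an estimated correlation). Of 27 gas vesicle genes 2 fell; adjusted over the list alone 1 rose and 12 fell (adjusted p = 1.9e-05; adjusted p = 0.641 with an estimated correlation). Of 10 genes of glutamate and arginine-related metabolism, gdhB (1.32), encoding a glutamate dehydrogenase, rose, and adjusted over the list alone 6 did (adjusted p = 0.0126; adjusted p = 0.641 with an estimated correlation). With 0 members past the gene test, lists called toward higher values were those of the NADH dehydrogenase-like complex (median 0.81, adjusted p = 0.00582; adjusted p = 0.748 with an estimated correlation), aminoacyl-tRNA synthetases (0.28, adjusted p = 0.00244; adjusted p = 0.748 with an estimated correlation) and the citric acid cycle (0.33, adjusted p = 0.00992; adjusted p = 0.666 with an estimated correlation). The same held for RNA polymerase (0.51, adjusted p = 0.0282) and archaella and chemotaxis (0.39, adjusted p = 0.0288), both at adjusted p = 0.641 with an estimated correlation. Adjusted over the list alone, 4 genes of the NADH dehydrogenase-like complex rose and 1 fell, and 1, 5, 3 and 0 genes rose in the other lists in this order.

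Other genes lower with arginine were vng2626 (-2.86), vng1007 (-1.66), vng5170 (-1.65), vng5109 (-1.63) and vng5040 (-1.62), and vng584 (1.36) was higher. The values of vng5114 (-2.68), vng5015 (-2.41), vng112 (-2.37) and vng5253 (-1.83) are uncertain because of shared probe sequences. The value of dmsA was 1.49 ± 0.40 (adjusted p = 0.119). In all, limma called 19 genes, 7 higher and 12 lower, a share of 36.8% higher that became 75% of 4 calls with median centring and 60% of 5 calls with the recorded log ratio. The count was 0 without any of the dmsR, TMAO against O2 or arginine against TMAO arrays or with growth and dmsR arrays fitted apart, 563 or 555 without replicate 1 or 2 of arginine against O2, 317 in the planned fit and 862 with no dye coefficient.

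**Figure D1:**
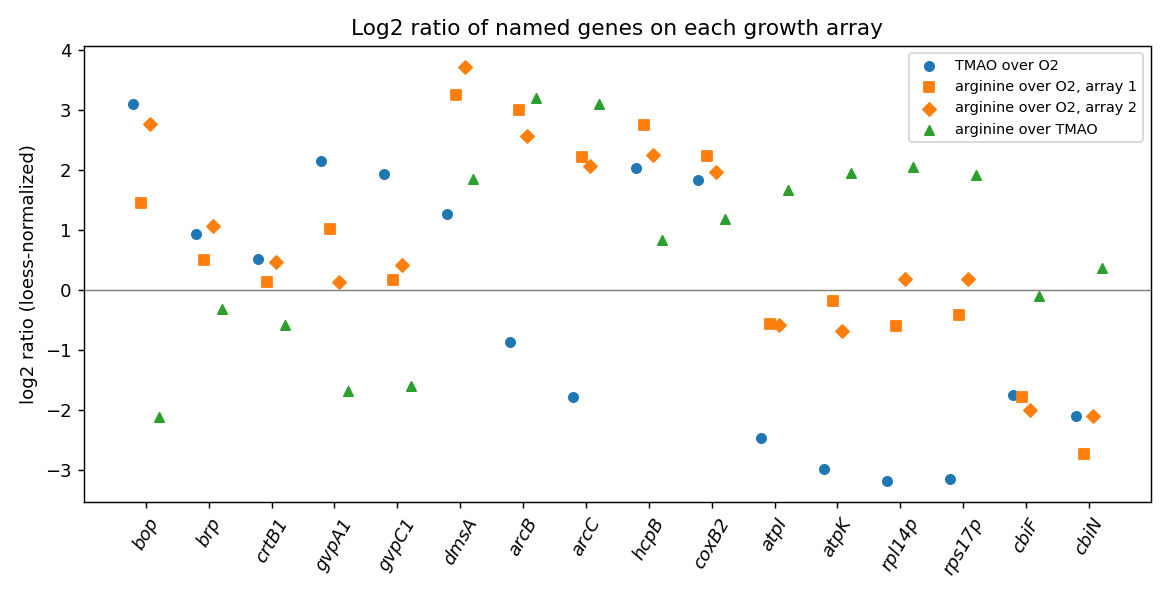
Loess-normalized log2 ratio of 16 named genes on each of the 4 growth arrays, each point 1 array, with ratios turned so that the first-named condition stands over the second. The arginine fermentation genes arcB and arcC lie above 0 on the arginine arrays and at -0.87 and -1.78 on the TMAO over O2 array, and bop stands at 3.10 on that array.

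The 3 growth comparisons form a closed loop. Across 2475 genes, which are not independent replicates, the arginine against TMAO array correlated with the difference of the other comparisons at Pearson r = 0.85 and Spearman rho = 0.78, with a covariance of 0.257. Both sides carry dye effects of the same sign, and in 100 simulations with no effect, the fitted dye term and the spread between arrays gave a mean r of 0.17, a highest r of 0.29 and a mean covariance of 0.0145. This does not test the label of the array scanned under 2 labels, which itself correlated at 0.77 with the arginine against TMAO array as Cy5 over Cy3. The TMAO and arginine effects against O2 correlated across genes at r = 0.45 and rho = 0.38, with a covariance of 0.0923. In 100 simulations with no effect, the shared arrays and dye term gave a mean r of -0.01 and a mean covariance of -0.000355. These simulations leave out that both effects are differences from the same O2 condition. Genes particular to O2 growth would alone give a positive correlation, and more shared calls than independent lists. The values here and below therefore do not show a common response to TMAO and arginine. Both effects were positive and called in 9 genes, among them dmsA, hcpB, coxB2, coxA1 and nhaC3, where independent lists would give 2.16. Both were negative and called in 12 genes, among them nrdA, nrdB1, carA, korA and 5 cobalamin genes, where independent lists would give 1.41. The gene arcC was called in opposite directions.

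In the dmsR deletion, limma called none of the genes it tested as different from the parent. The genes with large recorded ratios, dmsA among them, rested on spot records unlike the rest of their scans, and these records were left out. The deletion removes a regulator named for the dms genes. The files name no probe dmsR, and whether a gene known only by its number, such as vng826, is the targeted one is not known, so the labels were not checked by it. Limma called 0 of 2479 genes, with 3 at an unadjusted p under 0.05. The genes dmsA, vng828, hmoA, moz and vng832 are not among those tested, since all their records on these arrays were left out. The fit therefore does not show whether they differ. Over the 2477 genes outside those records, the 2 arrays correlated at r = 0.53 as Cy5 over Cy3 and at -0.53 after turning the swapped array, so their common pattern followed the dyes. Directions below are for the library labelled dmsR deletion over its parent, and the authors' deposited column runs the opposite way (r = -0.82).

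The largest same-sign values that did not pass were 0.42 ± 0.13 for entry3039, 0.21 for vng194, 0.18 for rpl14p, 0.16 for vng2166 and 0.16 for atpK, and -0.67 ± 0.10 for entry3019, -0.28 for vng659, -0.20 for entry3002, -0.19 for rps10p and -0.19 for rps9p (adjusted p = 1 for each). With the sign turned to the deposited direction, each of these changes sign. The gene entry3019 was called, as 1 gene, without either arginine against O2 array; its log2 ratio was -1.30 on 1 dmsR array and -0.04 on the other. The arginine fermentation genes had values of -0.17 (arcB), -0.18 (arcA), -0.04 (arcC) and 0.01 (arcR), and the list was called toward lower values (adjusted p = 8.1e-04; adjusted p = 0.641 with an estimated correlation). Its direction turned without dmsR replicate 1. Terminal oxidases (median -0.02, adjusted p = 0.0288; adjusted p = 0.641 with an estimated correlation) and surface and export genes (median -0.02, adjusted p = 0.0427; adjusted p = 0.641 with an estimated correlation) were also called, with directions that turned without replicate 2 and replicate 1. In these 3 lists, 0 genes passed the gene test, also adjusted over the list alone. Purple membrane genes lay between -0.02 (brp and crtB1) and 0.04 (blh), with bop at 0.01, blp at 0.03 and bat at -0.00. The fitted dmsR and TMAO effects were uncorrelated across genes (r = -0.04, rho = 0.01).

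The values of dmsA and 6 other genes depended on 25 spot records in each dmsR file. In the array design these genes have close numbers, from 826 to 834, with dmsA at 829. The recorded median log2 Cy5 over Cy3 of these records was -2.94 and 2.7 for dmsA on the 2 arrays, -4.73 and 5.83 for vng826, -2.6 and 4.35 for vng828, -2.0 and 2.05 for hmoA, -1.94 and 1.79 for moz, and -1.44 and 1.52 for vng832. By the dye labels these are higher in the library labelled dmsR deletion. In 7 of the replicate 1 records, mean signal less background was not the recorded subtracted signal. Over all records of replicate 2, 2 held identical signals, and this count does not show whether they are among these 25. With the records kept, the fit of the recorded log ratios called dmsA (2.65 ± 0.16, adjusted p = 0.00438) and vng828 (3.11 ± 0.14, adjusted p = 0.00131). The mean signals of the same records were also background-corrected and loess-normalized, with weight 0 for these records in the loess curve. Their fit gave -0.73 for dmsA and -0.27 for vng828, with 0 genes called. The arrays differed: on replicate 1 and replicate 2, dmsA stood at -0.02 and -1.45, and vng828 at -0.02 and -0.52. In the authors' deposited table these genes were lower in the deletion, at -5.10 for vng826, -3.56 for vng828, -2.81 for dmsA, -1.76 for hmoA, -1.60 for moz and -1.53 for vng832, and they were its 6 genes at or beyond 2-fold.

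**Figure D2:**
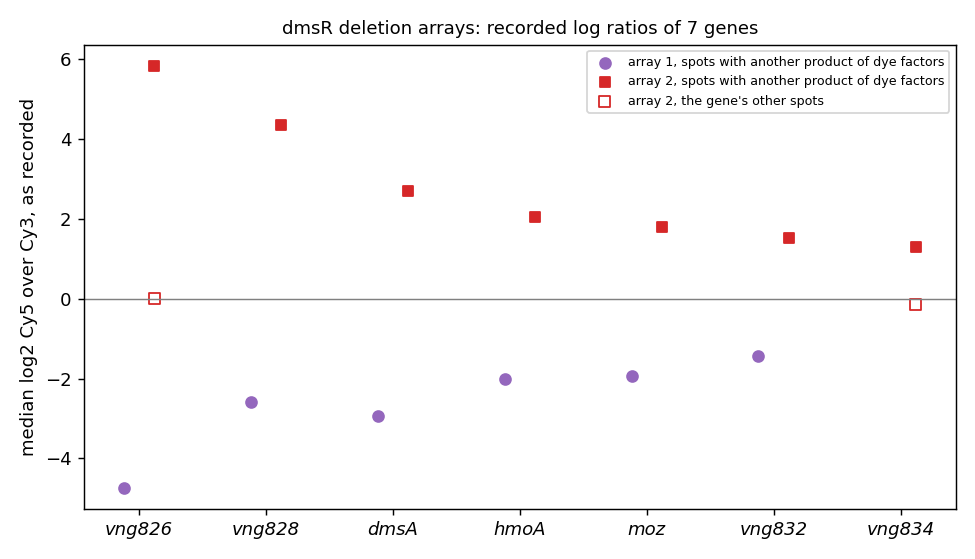
Recorded median log2 Cy5 over Cy3, without further normalization, of the 7 genes with such spot records on the 2 dmsR arrays, which carry opposite dyes. Filled points are the records with another product of dye factors and open points the gene's other spots on array 2, which stand at -0.0 for vng826 and -0.14 for vng834.

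In the bat deletion, the authors' deposited table showed purple membrane genes far below the parent. The bat gene encodes the activator of bacterioopsin. Directions are those of the column's label, which was not checked against scans, and with the column turned each value changes sign. The targeted gene itself stood at -1.13, and whether its probes lie in the deleted part is not known, so it checks the label only in part. The lowest value was that of bop at -5.82, 56.6-fold lower. The genes blp (-3.57), brp (-2.89) and crtB1 (-2.81) were also lower, and blh stood at -0.42. Of 6 purple membrane genes, 5 lay at or beyond 2-fold lower and 0 higher, with a median of -2.85. Both the 5 and the median include bat itself, the targeted gene. The genes vng1468 (-3.34) and vng1459 (-3.10) were as low, followed by vng2353 (-1.99), vng1788 (-1.96), vng378 (-1.93) and vng2248 (-1.92).

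At the other end of the authors' deposited table stood entry3009 (2.90) and entry3040 (2.47), vng6291 (2.41), vng311 (2.36), yuiH (2.05), vng1270 (1.96), vng5131 (1.93), vng119 (1.82), vng2380 (1.80) and sirR (1.73). The arginine fermentation genes were at 0.64 (arcB), 0.55 (arcA), 0.27 (arcR) and -1.10 (arcC), and dmsA was at 0.09. Of 27 gas vesicle genes, 1 lay at or beyond 2-fold higher and 1 lower, and of 55 ribosomal protein genes 0 higher and 2 lower. Over all 2484 genes, 75 were at or beyond 2-fold higher and 119 lower in the direction of the label. With the column turned, these 2 counts change places. The authors merged 2 arrays of 1 dye orientation, per the labels, so these values have no spread and no test. With 1 dye orientation, a dye effect particular to a gene cannot be told apart from an effect of the deletion.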

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

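The tests on the spot records, on the 2 scans of 1 array and on the direction of the dmsR column were chosen after the result was seen, and those on arcC were planned. In each dmsR file, 25 spot records carried a product of Cy3 and Cy5 dye factors unlike the rest of the scan. In replicate 1 the product was 303.9 in the other records and 569.5 in 18 of these, and in replicate 2 it was 213.1 against 217.4 in 24 of them. The lowest Cy5 local background among these records of replicate 1 was 55.0, and all 50 records lay above the 99th percentile of the other records of their file, so an origin in another scan or file is a candidate explanation. Against an expression difference measured in the same scan, these records made up 32.4% of the 148 spots beyond 2-fold on the dmsR arrays, compared with 0.0% of 3808 on the growth arrays. The shared product of 569.5 leaves open whether the records came from a further scan of the same samples, in which case the differences at dmsA may be biological; the files at hand do not hold such a scan.

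The TMAO against O2 scan and replicate 1 of arginine against TMAO carry different labels for Cy3, while deviations of repeated spots from their probe means correlated at 0.99 in Cy3 between them. Separate hybridizations of like samples are argued against by the other 20 pairs, where the highest such correlation was 0.32, so a repeated scan of 1 array is the candidate explanation that remains. After subtraction of the other arginine against TMAO array, the log2 ratios of this array correlated across 2481 genes at r = 0.61 and 0.63 with the 2 arginine against O2 arrays, where a Cy3 sample grown with arginine and like that of the other array predicts about 0, so that reading is argued against. An arginine culture with transcript levels near those of aerobic cells stays open and was not tested. Read as arginine against TMAO, the array gave 427 genes for TMAO against O2 and 0 for arginine against O2.

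Outside the records above, the deposited dmsR column correlated at -0.82 with the ratios turned by the dye labels. Exchanged dye labels of the dmsR arrays and a turned deposited column both predict this value and cannot be told apart, because which probe, if any, measures the deleted gene is not known. If vng826 were that gene, its recorded medians, -4.73 with the deletion in Cy3 and 5.83 with it in Cy5 by the labels, would go with exchanged labels, since a deleted gene should be lower. Its identity was not tested, so either explanation may account for the direction.

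The gene arcC was higher with arginine than with TMAO by 3.07 on the log2 scale (adjusted p = 0.0222), and its effects against O2, 1.78 with arginine and -1.29 with TMAO, were called in opposite directions.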

How the results depend on the processing

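The 6 alternatives on the double scan and the left-out spot records, the closure over both arginine against TMAO scans or without the dye effect, the simulated closure with no effect and the kept records in the dmsR and TMAO correlation were chosen after seeing the data; the others were planned. Counts of called genes depended on the settings. From 627 for TMAO against O2, 28 for arginine against O2 and 19 for arginine against TMAO they became 1012, 356 and 862 with no dye coefficient, 1014, 109 and 399 with array weights, and 0 for each with the dmsR arrays averaged or fitted apart. For the growth comparisons, averaging the dmsR arrays, fitting them apart and leaving out either one are 1 and the same fit. A lone or averaged dmsR array is fitted exactly and adds nothing to the spread, so these alternatives count once. With a log2 ratio of at least 1 asked for, 197 remained for TMAO against O2. Median centring gave 417 for TMAO against O2. For arginine against TMAO, median centring gave 4, the recorded log ratio 5 (also with the records kept), no background correction 8, the dim-probe filter 31 and means over probes 43. For arginine against O2 and arginine against TMAO, 7 scans gave 0 and 313, the planned fit 0 and 317, the double scan read as arginine against TMAO 0 and 83, and the other scan of that array 48 and 99. Leaving out 1 array gave 0 to 982, 0 to 313 and 0 to 563 genes, and 0 to 1 for the dmsR deletion. The dmsR count of 0 became 2 with the records kept and the recorded log ratio. Aquantile scaling leaves log ratios as they are, so its equal counts say nothing of stability. Leaving out 1 array leaves 1 residual degree of freedom in each case, but not the same one. Without a dmsR, TMAO against O2 or arginine against TMAO array, the spread rests only on the difference between the 2 arginine against O2 arrays. These had the lowest array weights, 0.52 and 0.46. Without 1 of these, it rests only on the agreement of the dye effect between the growth and dmsR arrays. The former left no calls for TMAO against O2 and the latter more than the main fit. Why the 2 spreads differ was not tested.

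Genes at or beyond 2-fold numbered 53, 169 and 0 in the fit for arginine against O2, arginine against TMAO and the dmsR deletion, and 84, 35 and 6 in the authors' deposited table. Of 112 list tests, 28 were called, and 0 with an estimated correlation, whose smallest adjusted p was 0.641. The latter test has fewer degrees of freedom, so whether correlation made the calls is open. Called lists had estimates from -0.14 to 0.49 (preset 0.01), with 0.16 for ribosomal proteins. ATP synthase, at 0.00, went from camera p 5.7e-07 to 0.0354 in TMAO against O2. The 194 genes of the bat column at or beyond 2-fold became 822 at 1.5-fold and 42 at 3-fold. Loop closure of 0.85 became 0.84 with the recorded log ratio, 0.69 with median centring, 0.86 without the dye effect of the dmsR arrays and 0.83 with both scans; in the last the double-scanned array stands on both sides, so it says nothing of closure. The correlation of dmsR and TMAO effects turned from -0.04 to 0.02 with the recorded log ratio and to 0.06 with the records also kept. The 85 named calls kept their sign under all 22 alternatives. They were chosen as past the threshold, many of them also with the same sign on all arrays of their comparison, so a kept sign says little of stability. All 85 missed the threshold with the dmsR arrays averaged, fitted apart or either left out. For these calls those alternatives are the same fit. Without the TMAO against O2 or the arginine against TMAO array, 84 missed the threshold. With the double scan read as arginine against TMAO 30 did, with 7 scans 25 and in the planned fit 24. Median centring lost 19, the recorded log ratio 14 (13 with the records kept) and no background correction 10. Means over probes and the other scan lost 2 each.

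No paired analysis was possible because each comparison lies within arrays and the replicate numbers tie no arrays across comparisons. The slide as a random block could not be fitted, since the estimated correlation was undefined for each gene. Signal over background was 2.48 to 3.7 on the dmsR arrays and 5.06 to 37.82 on the growth arrays, and the filter on dim probes left the dmsR count at 0.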

Other observations

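The genes in this paragraph were chosen after their values were seen. With TMAO, genes of nitrogen metabolism went both ways: gdhB (-1.79), gdhA2 (-1.26), ocd1 (-1.14) and glnA (-1.11), which encodes glutamine synthetase, fell, while argH (0.72), encoding argininosuccinate lyase, rose. Of the 10 genes of this list 1 rose and 4 fell, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.0883). Thermosome subunit genes split, with cctA at -1.49 and cctB at 0.74, both past the test; of 11 chaperone genes 3 rose and 3 fell. Of 27 gas vesicle genes 10 rose, and gvpL1 was the 1 that fell, at -1.85 (adjusted p = 0.00616). Peptide transporter genes dppB1 (-1.99), dppC2 (-1.71) and oppD2 (-1.44) fell while oppD1 (0.66), appA (0.61) and appB (0.56) rose; of the 19 genes of the peptide and amino acid transport list 4 rose, 3 fell and 12 did not pass, with the same counts adjusted over the list alone, and the list was not called (adjusted p = 0.939). The superoxide dismutase gene sod1 fell at -1.25 (adjusted p = 0.0334).

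Genes named in more than 1 comparison include vng1468, at 1.87 with TMAO and at -3.34 in the bat column of the authors' deposited table, beside bop at 3.66 and -5.82. The ribonucleotide reductase genes nrdA (-2.29 with TMAO, -2.34 with arginine) and nrdB1 (-2.44 and -2.30) fell in both the TMAO and the arginine cultures. The difference between these cultures was not called for either gene.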
